A study of Mus musculus with 12 samples.

How the data were processed

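Bulk RNA sequencing measured total RNA of 12 subcutaneous mouse PDAC tumour samples in 4 groups of 3: untreated, anti-IL-1R1, CD40 agonist, and both antibodies. Per the labels, the antibodies were injected into the peritoneum 2 times a week, the tumours were homogenised in liquid nitrogen, and RNA was taken up in TRIzol and purified with chloroform and isopropanol. The submitters' notes name the mm39 genome and DESeq2, without versions. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. Groups were taken from the sample labels, and the numbers in the sample titles were used as replicate numbers.

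The authors deposited 3 pairwise tables of 6 libraries each: combination against CD40 agonist (27880 genes), anti-IL-1R1 against untreated (29098 genes) and CD40 agonist against untreated (29014 genes). Per the file headers, each table gives raw counts per gene and library, which are the values used here. The deposited tables also give the authors' normalized counts and FPKM, gene length in bases, the authors' log2 fold changes (log2), a p-value (p_value) and an adjusted p per gene from the authors' DESeq2 test, and gene annotation with mm39 coordinates. The authors listed only genes with at least 2 reads over the 6 libraries of a table, and the authors' p-value was missing for 178, 9 and 78 genes of the 3 tables, where the adjusted p was set to 1. The normalized counts and FPKM, 42 columns of values, were not used here. The authors' log2 fold changes and adjusted p were used only to count and compare their calls at an adjusted p under 0.05. Counts of libraries present in 2 tables were checked and had 0 mismatches.

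The tables were joined on the 25894 genes present in all 3, out of 31106 in any. Of the 5212 genes left out, 13 had at least 100 reads in a library, and the largest count was 788, of Igkv10-94 in combination 1. Library totals ran from 27.8 to 53.3 M reads in genes. Rn18s-rs5, the only ribosomal RNA gene counted for this, took 0.51 to 4.1% of reads and mitochondrially encoded genes 1.44 to 2.5%. The common dispersion was 0.199, a biological coefficient of variation of 0.446, with 8 residual degrees of freedom. Every pair of libraries differed by more than counting noise, with a lowest median chi-square per gene of 11.4 over genes with at least 20 reads, so no 2 libraries were copies of each other.

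Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust estimation, TMM factors and the filterByExpr filter on the groups, which left 19436 genes in a fit of all 12 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 6 tests were anti-IL-1R1 and CD40 agonist against untreated, combination against each of the other 3 groups, and the interaction. All adjusted p of single genes come from edgeR unless another tool is named. The text uses CPM on TMM-scaled totals. For a gene without reads in a group, fold bounds were computed against 3 reads over the group, which covers counting error only.

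Gene lists, 36 in number with 601 genes, were fixed before the data were examined, as were the groups, the comparisons, the tests and the alternatives listed first below. In all, 584 of the genes were in a table. The 34 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over lists, and 2 lists, for eosinophils and for pancreatic acinar cells, had too few tested members. The lists were also tested with the correlation estimated per list and with fry. List levels are the mean log2(CPM + 0.5) of the tested members. A list with a member without reads in a group also had its median computed with that member at its bound, which moved none of the 24 medians concerned by more than 0.3. Members were also adjusted over their list alone. Members of gene families and paralogs share reads to an unknown degree, and multigene families are reported as uncertain, among them granzyme, Oas, Ifi200, Irgm, Gbp and ribosomal protein genes.

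The 2 correlations of effects used log2 CPM with a prior count of 2, and their exact permutation p comes from the 100 relabellings within the 2 independent pairs of groups. The 2 contrasts of a correlation share no library.

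Named genes followed a rule. Per comparison they were up to 8 higher and 8 lower genes with the largest log2 fold change among those with an adjusted p under 0.05 and a mean of at least 1 CPM, with no overlap between the libraries of the groups and a named symbol. The number was 5 and 5 for the comparisons without a deposited table and for the interaction. Where fewer than 5 genes passed, the 5 with the lowest p were named, and of each described list up to 4 members with the lowest p. Il1r1, Il1a, Il1b, Cd40 and Cd40lg were named throughout. Among the list members chosen by the rule, 1 is not reported here. Genes of the fit with a replicate block, Acta1 and the genes of the closing section were chosen after their values were seen.

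Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means. Same-numbered untreated and anti-IL-1R1 libraries correlated at 0.23, 0.193 and 0.22, each best with its own number, so a block is reported for that comparison. Over all 18 pairs of same-numbered libraries, 6 exceeded 0.1 and 5 were best with their own number, with values from -0.527 to 0.307. The pairing of untreated with anti-IL-1R1 libraries was thus picked from these data and may be chance.

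The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a filter of at least 10 CPM in at least 3 libraries, a replicate block, only the 2 groups in the fit, and leaving out each library in turn. A further 4 were chosen after seeing the data: the union of genes over the tables, limma voom with sample weights and a variance free per group, leaving out the 2 libraries rich in muscle transcripts, and the block with only untreated and anti-IL-1R1 libraries in the fit. A fallback for tables without raw counts was not needed.

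The tests were tested on simulated data with the depths of these libraries and a dispersion per gene that was the same in all groups. The real groups differed in spread, with a median SD in log2 CPM of 0.165 in untreated and 0.368 in combination libraries. The simulated shares and false calls may therefore not carry over to them. For combination against untreated, edgeR called 29% of 100 genes planted at 2-fold and 66% of 100 at 4-fold with 4 false calls, DESeq2 45% and 79% with 49 false calls, and limma voom 27% and 65% with 2 false calls. Camera called a list planted at 2-fold (adjusted p 1.59e-33) and 0 of the other lists. The simulated genes were drawn independently of each other. This therefore does not show how often camera falsely calls lists whose genes vary together, as they can in tumours. For anti-IL-1R1 against untreated, where no change was planted, edgeR called 1 gene, with 812 at an unadjusted p under 0.05. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.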

Results

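Pancreatic ductal adenocarcinoma (PDAC) is a stroma-rich cancer that is usually poor in T cells. Here mouse PDAC tumours grown under the skin were profiled by bulk RNA sequencing. Each library therefore mixes the transcripts of tumour cells, fibroblasts, vessels and infiltrating immune cells. The 12 libraries formed 4 groups of 3: untreated tumours, tumours treated with an antibody that blocks IL-1R1, tumours treated with an agonistic antibody against CD40, and tumours treated with both antibodies, called the combination here. IL-1R1 is the receptor through which the cytokines IL-1 alpha and IL-1 beta signal, and CD40 is a receptor of antigen-presenting cells whose stimulation equips them to activate T cells. The comparisons address what blocking IL-1R1 does to the tumour tissue, alone and on top of CD40 agonism.

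In M reads in genes, the untreated libraries held 53.3, 35.4 and 37.6 and the anti-IL-1R1 libraries 39.2, 27.8 and 42.6 (replicates 1, 2 and 3 in that order). The CD40 agonist libraries held 47.9, 37.0 and 43.9, and the combination libraries 37.8, 38.3 and 45.5. Levels are given in CPM, counts scaled to a common library total, as mean ± SD with n = 3 libraries per group unless stated. Untreated libraries were the most alike, with a median SD of 0.165 in log2 CPM over the 14378 genes with a mean of at least 1 CPM. It was 0.299 in the anti-IL-1R1 group, 0.247 in the CD40 agonist group and 0.368 in the combination group. No source states that the 3 libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

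Transcripts of the antibody targets were measured first. Il1r1 (ENSMUSG00000026072, chromosome 1, 40264240 to 40356417, mm39) lay at 67.6 ± 1.73 CPM in untreated tumours, 73.4 ± 8.22 with anti-IL-1R1, 69.6 ± 9.28 with CD40 agonist and 67.7 ± 8.89 in the combination, with no difference past the test in any comparison. The ligand gene Il1b (ENSMUSG00000027398, chromosome 2, 129206490 to 129213059) stood at 12.3 ± 0.835 CPM in untreated tumours and 12.1 ± 2.68 with anti-IL-1R1, and at 24.9 ± 7.41 and 25.4 ± 11.5 CPM in the groups that received CD40 agonist. Il1a (ENSMUSG00000027399, chromosome 2, 129141530 to 129151892) measured 0.863 ± 0.805, 0.809 ± 0.298, 4.04 ± 3.52 and 13.9 ± 14.0 CPM in the same order, and 1 library, combination 3, held 29.7 CPM. Cd40 (ENSMUSG00000017652, chromosome 2, 164897547 to 164914868) was at 4.66 ± 0.546 CPM in untreated and 4.70 ± 0.50 CPM in anti-IL-1R1 tumours, and at 18.5 ± 14.3 and 22.2 ± 3.46 CPM in the CD40 agonist and combination tumours. Only its difference between combination and anti-IL-1R1 passed the test over all genes (log2 fold change 2.24, SE 0.441, adjusted p 0.0254), while combination against untreated reached an adjusted p of 0.0631. Cd40lg, which encodes the ligand of CD40, was not among the tested genes.

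Mean levels of interferon-stimulated, antigen presentation and T cell genes were lower in tumours given anti-IL-1R1 alone than in untreated tumours. No single gene passed, and the list calls hung on the preset correlation, as given below. MHC class I list levels overlapped (6.08 in anti-IL-1R1 1 against 5.88 and 5.72 in untreated 2 and 3). T cell levels did too (0.84 in anti-IL-1R1 2 against 0.8 in untreated 2). All 30 tested members of the type I interferon list had negative fold changes, with a median log2 of -0.91, and so had all 27 members of the interferon gamma list, with a median of -1.02. Irf7, a transcription factor that amplifies type I interferon production, measured 31.1 ± 2.95 CPM in untreated and 10.3 ± 3.25 CPM in treated tumours, and the antiviral gene Oas3 5.53 ± 2.38 and 0.892 ± 0.476 CPM. Usp18, a negative regulator of interferon signalling, stood at 7.56 ± 1.28 and 2.84 ± 0.257 CPM, and Cxcl10, a chemokine that attracts activated T cells, at 28 ± 7.03 and 9.22 ± 3.03 CPM. Ido1, a tryptophan-degrading enzyme induced by interferon gamma, stood at 4.00 ± 2.36 and 1.02 ± 0.549 CPM, and Ciita, the master regulator of MHC class II genes, at 15.3 ± 6.18 and 6.28 ± 1.60 CPM.

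The same direction was seen in further immune lists of this comparison. All 19 MHC class I presentation genes were lower (median -0.67), among them the peptide transporter gene Tap1 with 85.3 ± 48.3 against 40.4 ± 31.2 CPM, and so were all 10 MHC class II genes (median -0.88). Of the 21 T cell genes 20 were lower (median -1.10), and Cd3e, a subunit of the T cell receptor complex, measured 1.05 ± 0.15 and 0.226 ± 0.262 CPM. Cytotoxic T and NK cell genes went both ways, with 9 of 20 higher (median -0.09, adjusted p 0.0974), and neither they nor regulatory T cells (adjusted p 0.0938) were called. All 19 macrophage and monocyte genes were lower by a smaller amount (median -0.35). Fcgr1, an activating antibody receptor, measured 12.0 ± 0.966 and 7.51 ± 1.64 CPM and the complement gene C1qc at 133 ± 31.0 and 88.9 ± 40.9 CPM. In the list of mediators induced by IL-1 and NF-kB, 17 of 24 members were lower (median -0.67). They included Csf1, a macrophage growth factor, at 54.0 ± 5.10 and 30.6 ± 8.27 CPM, and Tnf at 1.80 ± 0.716 and 0.511 ± 0.0795 CPM. Of the 5 genes with the lowest p, Gpr35, the clock gene Per1 and Retn were lower at 12.8 ± 2.97 against 5.94 ± 1.22, 73.8 ± 3.42 against 47.2 ± 9.53 and 0.567 ± 0.443 against 0.0313 ± 0.0359 CPM. Adam28 and Zfp268 were higher at 0.244 ± 0.183 against 1.41 ± 0.358 and 1.36 ± 0.302 against 3.69 ± 0.731 CPM. Zfp268 belongs to a large zinc finger family and Oas3 to a small family of related genes, so their reads are uncertain.

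No single gene passed the test in this comparison. edgeR's quasi-likelihood test called 0 of 19436 genes, with every adjusted p at 1 and 304 genes at an unadjusted p under 0.05, where chance gives about 972. DESeq2 and limma voom also called 0 genes. With only these 2 groups in the edgeR fit, 827 of 17703 genes had an unadjusted p under 0.05. With limma voom it was 702 of 19436 and with DESeq2 418 of 19328. The count of 304 comes from a spread shared over all 4 groups, so it does not show less change than chance. As groups, 18 of the 34 tested lists passed camera with a preset correlation, 17 lower and 1 higher, led by type I interferon (adjusted p 1.09e-17), interferon gamma (adjusted p 1.35e-14) and T cell genes (adjusted p 3.23e-10). None passed with an estimated correlation, where the adjusted p of the called lists ran from 0.301 to 0.658, and adjusted over the list alone no member of the lists described here passed. The cell cycle list, the 1 list called higher (median 0.12), lost its call without untreated 1 (adjusted p 0.558) or anti-IL-1R1 3 (adjusted p 0.62). The B and plasma cells list (median -1.25) was called lower with all libraries and higher without untreated 3 (adjusted p 0.0254). It was not called without anti-IL-1R1 1 (adjusted p 0.464) or anti-IL-1R1 2 (adjusted p 0.297). Markers of other tissues moved as well. The erythroid cells list had 5 of 5 genes lower (median -0.75, adjusted p 0.00456, adjusted p = 0.301 with an estimated correlation), a call lost without anti-IL-1R1 1 (0.0504) or anti-IL-1R1 3 (0.117). Of 18 skeletal muscle genes 15 were higher (median 1.19, adjusted p 0.0593), which did not pass.

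Same-numbered untreated and anti-IL-1R1 libraries deviated together from their group means, so both forms of a replicate block are given. Over all groups 5 of 18 same-numbered pairs were best with their own number, so this pairing may be chance. With the block in a fit of all 12 libraries, edgeR again called 0 genes. With the block in a fit of these 6 libraries alone, which leaves 2 residual degrees of freedom and was chosen after the data were seen, edgeR called 27 genes, 4 higher and 23 lower, and camera called 20 lists, 3 higher and 17 lower. Of the 15 alternative fits for this count, that fit was the only 1 with a call. The lower genes included the complement genes Cfd (log2 fold change -2.84, adjusted p 0.00065) and C3 (-1.06, adjusted p 0.0299) and the acute phase gene Hp (-1.94, adjusted p 0.000871). Interferon and antigen presentation genes among them were Cxcl10 (-1.62, adjusted p 0.00203), Irf7 (-1.61, adjusted p 0.0029), Tap1 (-1.23, adjusted p 0.0096), the MHC class II chaperone gene Cd74 (-0.95, adjusted p 0.0416) and Isg15 (-1.24, adjusted p 0.0321). The 4 higher ones were Csrp3 (4.26, adjusted p 0.0301), the ribosomal protein gene Rpl21 (1.07, adjusted p 0.0301) and the granzyme genes Gzmf (1.59, adjusted p 0.0098) and Gzmd (1.15, adjusted p 0.0321). Rpl21 and the granzymes, which are close relatives of each other, are uncertain. In this comparison camera without a block called the adipose tissue list lower (adjusted p 0.00319, 0.404 with an estimated correlation), and 15 of 18 skeletal muscle genes were higher. Whether tissue beside the tumour accounts for any of the 27 genes was not tested. All 27 had an adjusted p of 1 without the block, and 11 were members of the interferon lists. For this comparison the authors' deposited table called 23 genes, 5 higher and 18 lower, of which 13 were among these 27. Both sets come from the same counts, so their overlap is no independent support.

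**Figure D1:**
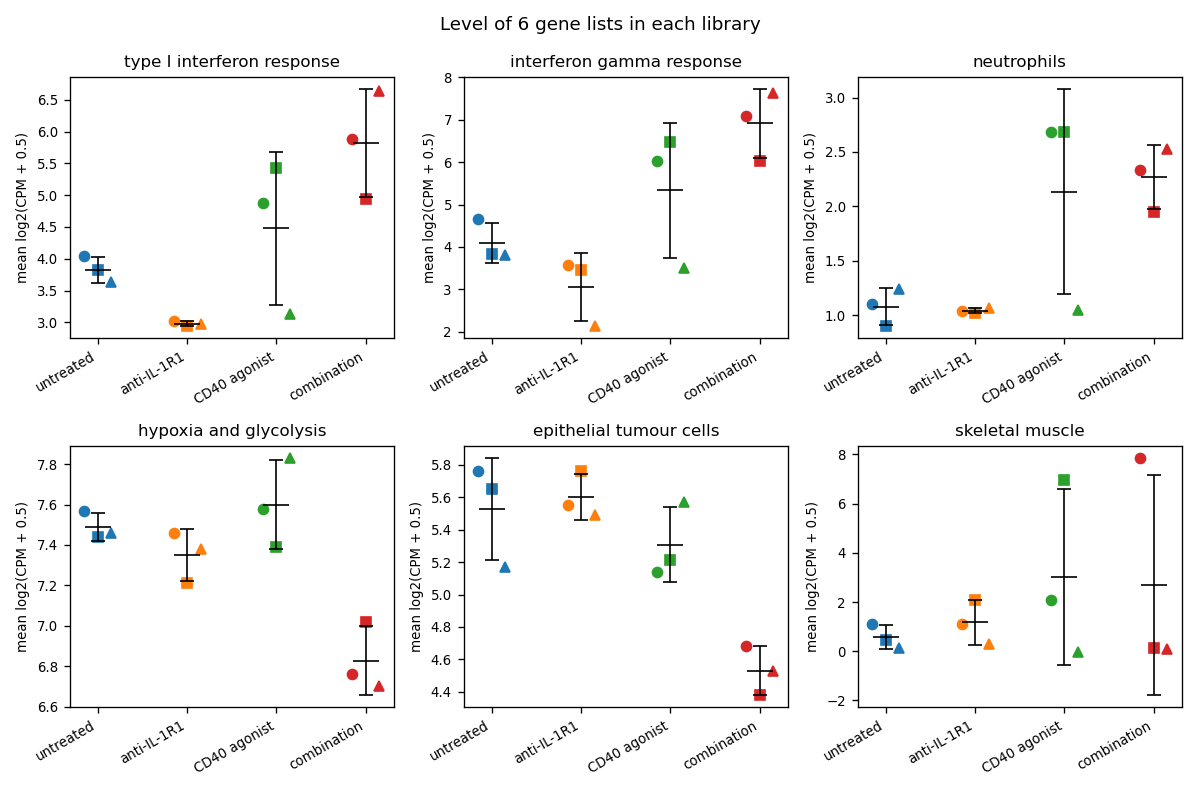
Level of 6 gene lists in each library, as mean log2(CPM + 0.5) of the tested members, by group; points are single libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are mean ± SD, n = 3. The type I interferon level lay between 2.95 and 3.03 in the anti-IL-1R1 libraries and between 3.63 and 4.04 in the untreated ones, and CD40 agonist 3 stood at 3.13 beside 4.88 and 5.42 in its group.

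CD40 agonist alone was accompanied by higher interferon, neutrophil and inflammatory transcripts than in untreated tumours in 2 of its 3 libraries. CD40 agonist 3 lay below all untreated libraries in the levels of both interferon lists and of the mediators induced by IL-1 and NF-kB, and within their range for neutrophil genes. All 27 interferon gamma genes had positive fold changes, with a median log2 of 1.70, and all 30 type I interferon genes, with a median of 1.01. The inducible nitric oxide synthase gene Nos2 stood at 7.46 ± 3.45 CPM in untreated and 40.4 ± 31.0 CPM in treated tumours, and Cxcl10 at 28 ± 7.03 and 112 ± 88.3 CPM. All 13 neutrophil genes were higher (median 1.87). Among them were S100a9 at 0.373 ± 0.0857 and 2.52 ± 1.75 CPM and S100a8 at 0.620 ± 0.260 and 4.57 ± 3.37 CPM, which encode the subunits of calprotectin. The gelatinase gene Mmp9 stood at 66.1 ± 49.8 and 343 ± 316 CPM.

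Of the 24 mediators induced by IL-1 and NF-kB, 23 were higher with CD40 agonist (median 1.39), including the monocyte chemokine gene Ccl2 at 16.1 ± 0.881 and 58.2 ± 40.9 CPM and the acute phase gene Saa3 at 7.32 ± 5.35 and 57.0 ± 46.5 CPM. In the list of CD40 and noncanonical NF-kB targets 18 of 23 members were higher (median 0.62), with Cd40 itself and Birc3, an inhibitor of apoptosis at 12.4 ± 0.657 and 23.1 ± 10.5 CPM, among its lowest p-values. All 20 cytotoxic T and NK cell genes were higher (median 1.15), with the pore-forming perforin gene Prf1 at 4.77 ± 2.57 and 13.4 ± 11.6 CPM. Cell cycle genes were higher in 29 of 30 cases by a small amount (median 0.31). The 5 genes with the lowest p were Cd40 (log2 fold change 1.99, SE 0.436), the myeloid receptor gene Clec5a (1.80, SE 0.398), Sirpb1b (2.12, SE 0.482), Calhm6 (3.14, SE 0.738) and S100a9 (2.74, SE 0.671), all with an adjusted p of 1. Sirpb1b has close paralogs, so its reads are uncertain. All 18 skeletal muscle genes were higher (median 5.89), which CD40 agonist 2 carried. The list level was 6.97 in it, 2.10 in CD40 agonist 1 and -0.02 in CD40 agonist 3, below every untreated library (0.15 to 1.11), and without the libraries rich in muscle transcripts the median was 1.29. Acta1, muscle actin, stood at 655 CPM in CD40 agonist 2, 27.3 CPM in CD40 agonist 1, 0.329 CPM in CD40 agonist 3 and at most 7.96 CPM in untreated libraries.

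For CD40 agonist against untreated edgeR called 0 genes, with 468 at an unadjusted p under 0.05. DESeq2 called 8 genes, all higher, limma voom 0, and edgeR called 8 genes, all higher, once CD40 agonist 3 was left out. The authors' deposited table called 16 genes, 12 higher and 4 lower. Camera with a preset correlation called 14 lists, 13 higher and 1 lower, led by interferon gamma (adjusted p 8.64e-20), with none called when the correlation was estimated (adjusted p 0.322 to 0.517 for the called lists). Of the 10 splits of these libraries, 6 called as many lists, the real one included, with 23 in the highest other. The number of lists called is therefore no evidence of an effect here. Adjusted over the list alone, 3 neutrophil genes, 1 CD40 target and 2 genes of alternatively activated macrophages passed, 1 of these 2 higher and 1 lower. CD40 agonist 3 differed from the other 2 libraries of its group, with Irf7 at 12.5 CPM beside 56.2 and 91.0 CPM. That is below the 3 untreated libraries (27.6 to 32.8 CPM) and within the range of the anti-IL-1R1 ones (8.00 to 14.0 CPM). Without it the median of the type I interferon list was 1.44, and without CD40 agonist 2 and combination 1, the libraries rich in muscle transcripts, it was 0.41. Without those 2 libraries the median of the cytotoxic T and NK cell list was 0.43 and that of the CD40 targets 0.17, and without CD40 agonist 3 that of the CD40 targets was 0.86. Without CD40 agonist 2 alone the call of the cytotoxic T and NK cells list was lost (adjusted p 0.0928), and without CD40 agonist 1 that of the IL-1 and NF-kB induced inflammatory mediators (adjusted p 0.0811).

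Adding anti-IL-1R1 to CD40 agonist was accompanied by lower hypoxia, glycolysis and epithelial transcripts. Interferon transcripts were higher on average, with overlap between the libraries of the groups. All 21 hypoxia and glycolysis genes were lower in the combination than with CD40 agonist alone (median log2 -0.78). The carbonic anhydrase gene Car9 stood at 92.5 ± 33.3 against 31.7 ± 14.4 CPM and the mitophagy receptor gene Bnip3 at 146 ± 38.9 against 76.5 ± 13.6 CPM. Pdk1, a kinase that restrains pyruvate oxidation, measured 139 ± 41.8 against 76.7 ± 1.67 CPM, and adrenomedullin (Adm) 54.7 ± 13.8 against 21.6 ± 9.05 CPM. Of the 18 epithelial tumour cell genes 17 were lower (median -0.54). The cytokeratin gene Krt19 stood at 804 ± 187 against 377 ± 142 CPM, the tight junction gene Cldn3 at 3.42 ± 1.02 against 0.978 ± 0.415 CPM and the galectin gene Lgals4 at 76.5 ± 47.4 against 17.2 ± 6.97 CPM. Epcam (ENSMUSG00000045394, chromosome 17, 87943407 to 87958557), an epithelial adhesion molecule, stood at 3.39 ± 1.47 CPM with CD40 agonist and 0.0769 ± 0.0678 CPM in the combination, where the 3 libraries together held 10 reads.

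Interferon genes went the other way. The median of the type I interferon list was 1.25 with 29 of 30 members higher, and that of the interferon gamma list 1.32 with all 27 higher. Type I interferon levels were 4.88, 5.42 and 3.13 with CD40 agonist and 5.89, 4.94 and 6.63 in the combination. Those of interferon gamma genes were 6.03, 6.47 and 3.51 against 7.08, 6.03 and 7.63, so both lists overlapped. The guanylate-binding protein gene Gbp2 stood at 495 ± 354 against 1504 ± 753 CPM, the immunity-related GTPase gene Irgm1 at 214 ± 133 against 523 ± 227 CPM, and Bst2, which tethers budding virus, at 227 ± 115 against 533 ± 259 CPM. MHC class I presentation genes were higher in 18 of 19 cases (median 1.05), with the proteasome activator gene Psme1 at 143 ± 35.9 against 250 ± 70.8 CPM, and Ifng, the interferon gamma gene, measured 1.49 ± 1.06 against 9.98 ± 9.38 CPM. Erythroid genes were lower in 5 of 5 cases (median -1.98), including the haemoglobin gene Hba-a1 at 5.51 ± 2.74 against 1.46 ± 0.492 CPM, whose reads are uncertain because Hba-a2 is nearly identical.

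The 1 gene that passed in this comparison was Diras2 (ENSMUSG00000047842, chromosome 13, 52658416 to 52685315), which encodes a small GTPase related to Ras. It fell from 16.1 ± 4.80 to 4.48 ± 0.590 CPM (log2 fold change -1.84, SE 0.239, adjusted p 0.0449), with 1290 genes at an unadjusted p under 0.05. With only these 2 groups in the edgeR fit that number was 502 of 17828. With limma voom it was 810 of 19436, where chance gives about 972. The count of 1290 comes from a spread shared over all 4 groups, so it does not show more change than chance. The call of Diras2, combination vs CD40 agonist, was lost without CD40 agonist 1 (adjusted p 0.101), CD40 agonist 3 (0.235), combination 1 (0.0641), combination 2 (0.057) or combination 3 (0.0839), and 5 other genes were called without combination 1. Next in rank, each with an adjusted p of 0.214, came Epcam and 3 genes without a read in the combination, which were at least 37.7-fold (Lrrc26), 31.0-fold (Egfros) and 40.9-fold (Gm49526) lower than with CD40 agonist, as computed against 3 reads over the group. This bound and those below cover counting error only, since they take reads as independent molecules, which the shares of odd counts in the combination libraries (36.1 to 38.8%, where independent reads give 50%) speak against. Egfros is antisense to another gene and strand use is not stated, so its reads are uncertain. With a replicate block edgeR called 0 genes, with 993 at an unadjusted p under 0.05. DESeq2 called 101 genes, 6 higher and 95 lower, limma voom called 0, and the authors' deposited table called 22, 1 higher and 21 lower. All 22 had the same sign and an unadjusted p under 0.05 here. Those calls were made from the same counts, so this match is no independent support.

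Among the lists of combination against CD40 agonist, camera called 21, 16 higher and 5 lower, with hypoxia and glycolysis at an adjusted p of 2.41e-27, type I interferon at 9.58e-22 and epithelial tumour cells at 5.87e-12. With an estimated correlation these stood at adjusted p = 0.0561, 0.309 and 0.113, and no list passed. By fry, which tests whether the genes of a list move on balance one way, hypoxia and glycolysis (adjusted p 0.0143) and epithelial tumour cells (adjusted p 0.0463) passed and no other list did. Adjusted over the list alone, 17 hypoxia genes, 4 epithelial genes, 3 erythroid genes, 1 immediate early gene and 1 Schwann cell gene passed, all lower, and 0 interferon genes. Without CD40 agonist 3 only 8 lists were called, 5 higher and 3 lower, and the medians of type I interferon, hypoxia and epithelial genes became 0.84, -0.65 and -0.41. Those of interferon gamma and MHC class I presentation genes became 0.81 and 0.67, a drop of more than 1.5 times.

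Combination tumours differed from untreated ones in both directions at the level of single genes. Genes of myeloid cells were among the higher ones, and epithelial and hypoxia genes among the lower ones. Clec5a (ENSMUSG00000029915, chromosome 6, 40551828 to 40562755), an activating receptor of monocytes and neutrophils, rose from 3.81 ± 0.434 to 26.9 ± 11.3 CPM (log2 fold change 2.82, SE 0.412, adjusted p 0.0395). Bst1 (ENSMUSG00000029082, chromosome 5, 43976227 to 44001328), an ectoenzyme that hydrolyses NAD, rose from 3.04 ± 0.767 to 26.5 ± 11.0 CPM (3.12, SE 0.482, adjusted p 0.0395). Sirpb1b (ENSMUSG00000095028, chromosome 3, 15560811 to 15640125) rose from 0.343 ± 0.0618 to 3.24 ± 0.885 CPM (3.23, SE 0.498, adjusted p 0.0395). The macrophage membrane gene Ms4a6d (ENSMUSG00000024679, chromosome 19, 11563968 to 11582213) rose from 23.9 ± 2.30 to 73.7 ± 17.6 CPM (1.63, SE 0.261, adjusted p 0.0405). Sirpb1b and Ms4a6d have close paralogs and are uncertain to that extent.

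On the lower side Diras2 fell from 18.9 ± 1.14 to 4.48 ± 0.590 CPM (log2 fold change -2.07, SE 0.241, adjusted p 0.0125). Epcam fell from 6.53 ± 5.55 to 0.0769 ± 0.0678 CPM (-6.31, SE 0.885, adjusted p 0.0395). Car9 (ENSMUSG00000028463, chromosome 4, 43506966 to 43513729), a surface enzyme induced by low oxygen, fell from 133 ± 31.2 to 31.7 ± 14.4 CPM (-2.07, SE 0.317, adjusted p 0.0395). Stc2 (ENSMUSG00000020303, chromosome 11, 31307307 to 31320074), a secreted glycoprotein also induced by low oxygen, fell from 5.59 ± 1.32 to 1.07 ± 0.201 CPM (-2.39, SE 0.367, adjusted p 0.0395). Lrrc26 (ENSMUSG00000026961, chromosome 2, 25179927 to 25181192), an auxiliary subunit of BK potassium channels in epithelia, was at 2.90 ± 1.90 CPM in untreated tumours and had no read in the combination, which makes it at least 119-fold lower as far as counting error goes (adjusted p 0.0395).

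Interferon, MHC class I presentation and cytotoxic lists were higher in combination than in untreated tumours, and epithelial and hypoxia lists were lower. Interferon gamma genes were higher in 27 of 27 cases (median log2 3.12) and type I interferon genes in 29 of 30 (median 2.33). The transcription factor gene Irf1 stood at 83.7 ± 21.0 in untreated and 471 ± 248 CPM in combination tumours, Parp14 at 46.4 ± 10.2 and 244 ± 106 CPM, Ifit2 at 10.7 ± 1.93 and 51.8 ± 26.5 CPM and Gbp2 at 152 ± 60.5 and 1504 ± 753 CPM. All 19 MHC class I presentation genes (median 1.69) and all 20 cytotoxic T and NK cell genes (median 2.16) were higher. Examples are Psme2 at 60.8 ± 2.51 and 192 ± 58.4 CPM and the granzyme gene Gzmb at 5.46 ± 1.44 and 35.4 ± 29.6 CPM. MHC class II presentation was not called, with 7 of 10 genes higher (median 0.38, adjusted p 0.15). Neutrophil genes were higher in 12 of 13 cases (median 1.99). CD40 targets were higher in 21 of 23 (median 0.86), among them the costimulatory ligand gene Cd80 at 3.40 ± 0.341 and 14.8 ± 9.10 CPM, and cell cycle genes were higher in 28 of 30 (median 0.48), among them topoisomerase Top2a at 97.0 ± 15.4 and 229 ± 95.9 CPM. Epithelial genes were lower in 17 of 18 cases (median -0.83) and hypoxia genes in 19 of 21 (median -0.60). Krt19 stood at 945 ± 132 and 377 ± 142 CPM and Vegfa, the vascular growth factor gene, at 343 ± 36.1 and 193 ± 29.1 CPM. Lists of other tissues were lower as well, namely erythroid (median -2.03, camera adjusted p 3.54e-05, fry 0.0314) and skin keratinocyte genes (median -1.27, camera adjusted p 0.0495).

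For combination against untreated edgeR called 12 genes, 4 higher and 8 lower, and 3009 had an unadjusted p under 0.05. DESeq2 called 1031 genes, 616 higher and 415 lower, which included all 12, and limma voom 50, 40 higher and 10 lower, which shared 7 with them. With a replicate block in the fit edgeR called 0 genes, with 2575 at an unadjusted p under 0.05. Single libraries decided the count, which was 0 without untreated 1 or untreated 2, 4 without untreated 3, and 118, 542 and 2 without combination 1, 2 and 3. Camera with a preset correlation called 18 lists, 14 higher and 4 lower, with type I interferon at an adjusted p of 1.37e-28 and hypoxia at 3.31e-12, and none passed with an estimated correlation (both at adjusted p = 0.154). By fry 12 lists passed, with epithelial and hypoxia genes at an adjusted p of 0.0155 and both interferon lists at 0.0481. Of the lists described here, adjusted over the list alone, 29 type I interferon, 25 interferon gamma, 17 MHC class I, 11 cytotoxic, 16 cell cycle, 10 CD40 target, 4 neutrophil, 10 epithelial and 14 hypoxia genes passed, against 1 epithelial and 1 hypoxia gene over all genes. Muscle transcripts were carried by combination 1, with Acta1 at 1560 CPM beside 0.160 and 0.278 CPM in combination 2 and 3. Without combination 1 and CD40 agonist 2 the count was 153 genes, 64 higher and 89 lower, including all 12, and the type I interferon and hypoxia medians were 2.30 and -0.65.

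**Figure D2:**
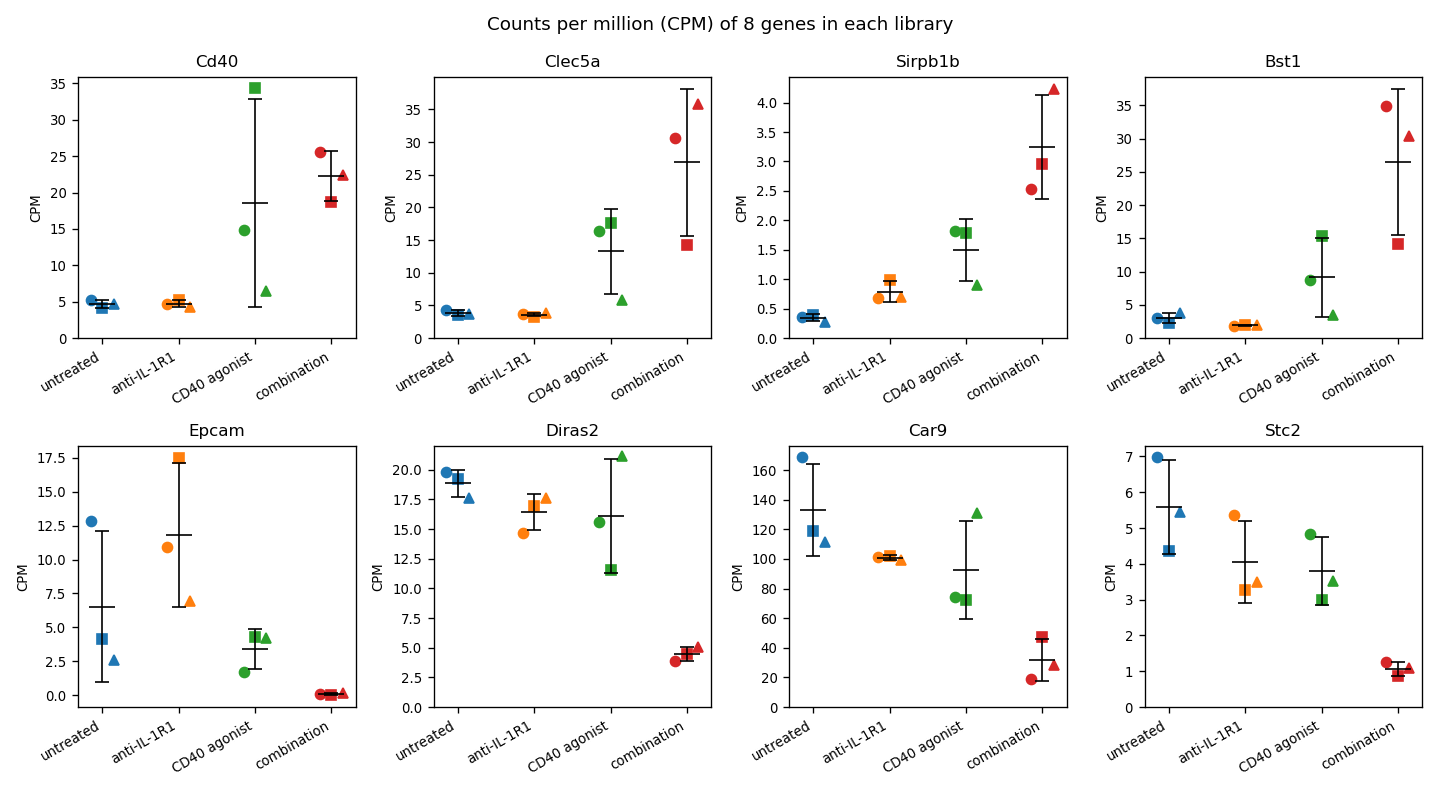
Level of 8 genes in each library in CPM, by group; points are single libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are mean ± SD, n = 3. Epcam lay between 0 and 0.128 CPM in the combination libraries and between 2.56 and 12.9 CPM in the untreated ones.

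Between combination tumours and those given anti-IL-1R1 alone edgeR called 474 genes. A wrong grouping of the same libraries, anti-IL-1R1 1 and 3 with combination 2 against the rest, called 445. The size of the count therefore does not by itself show an effect of the treatment. The largest increases were in Acod1 (ENSMUSG00000022126, chromosome 14, 103284413 to 103294009), which makes the antimicrobial metabolite itaconate and rose from 0.444 ± 0.257 to 44.9 ± 19.8 CPM (log2 fold change 6.70, adjusted p 0.035), and in Ly6i (0.408 ± 0.324 to 39.4 ± 22.2 CPM, adjusted p 0.0487). Increases of this size were also seen in Ifng (ENSMUSG00000055170, chromosome 10, 118276951 to 118281797; 0.112 ± 0.175 to 9.98 ± 9.38 CPM, adjusted p 0.0253) and the DNA sensor family genes Ifi206 (0.306 ± 0.179 to 22.7 ± 16.4 CPM, adjusted p 0.0345) and Ifi213 (0.322 ± 0.248 to 16.2 ± 12.3 CPM, adjusted p 0.0395). Ly6i, Ifi206 and Ifi213 belong to multigene families and are uncertain to that extent. The largest decreases were in Lrrc26, at least 144-fold lower as far as counting error goes (adjusted p 0.0149), the antimicrobial lectin gene Reg3b, from 15.1 ± 9.04 to 0.0356 ± 0.0616 CPM (adjusted p 0.0238), and Epcam, from 11.8 ± 5.31 to 0.0769 ± 0.0678 CPM (adjusted p 0.0149). The kinase gene Map3k21 fell from 4.73 ± 0.886 to 0.0426 ± 0.0738 CPM (adjusted p 0.0251), and Reg1 from 23.5 ± 27.2 to 0.312 ± 0.0950 CPM (adjusted p 0.0408). Reg1 and Reg3b have close relatives in the same gene cluster.

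All 30 type I interferon genes (median log2 3.40, 26 called over all genes) and all 27 interferon gamma genes (median 4.09, 13 called) were higher than with anti-IL-1R1 alone. Among them were Bst2 at 74.7 ± 24.8 and 533 ± 259 CPM, Usp18 at 2.84 ± 0.257 and 36.3 ± 28.3 CPM, Irgm1 at 51.6 ± 17.0 and 523 ± 227 CPM and Cxcl10 at 9.22 ± 3.03 and 308 ± 225 CPM. The called MHC class I presentation genes, 9 of 19, included the proteasome activator genes Psme1 (97.5 ± 18.4 and 250 ± 70.8 CPM) and Psme2 (59.4 ± 21.1 and 192 ± 58.4 CPM). CD40 targets were higher in 23 of 23 cases (median 1.46, 8 called), with Tnfaip3, a brake on NF-kB signalling, at 23.9 ± 2.34 and 66.4 ± 30.9 CPM. Macrophage genes were higher in 17 of 19 cases (median 1.05, 6 called), for example Fcgr1 at 7.51 ± 1.64 and 24.6 ± 5.09 CPM and the protease gene Ctss at 132 ± 22.6 and 385 ± 107 CPM. IL-1 and NF-kB induced mediators were higher in 22 of 24 (median 2.46, or 2.30 with Il23a, which had no read with anti-IL-1R1, at its bound, 5 called). Csf1 stood at 30.6 ± 8.27 and 126 ± 30.6 CPM, Ccl7 at 6.21 ± 1.62 and 45.5 ± 18.0 CPM and Tnf at 0.511 ± 0.0795 and 10.4 ± 4.75 CPM. T cell genes were higher in 20 of 21 cases (median 2.64), with none called over all genes and 14 adjusted over the list alone. Epithelial genes were lower in 17 of 18 cases (median -0.78, 4 called), with Lgals4 at 130 ± 25.1 and 17.2 ± 6.97 CPM, and hypoxia genes in 19 of 21 (median -0.47, 2 called, Car9 and Pdk1).

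For combination against anti-IL-1R1 edgeR called 367 genes higher and 107 lower, and 2832 had an unadjusted p under 0.05. DESeq2 called 1297, which included all 474, and limma voom 0. With a replicate block edgeR called 0 genes, with 2453 at an unadjusted p under 0.05. All 18 skeletal muscle genes were higher (median 5.34, adjusted p 0.0702), carried by combination 1. Without the 2 libraries rich in muscle transcripts that median was -2.40, the count was 556 genes, of which 368 were among the 474, and the type I interferon and interferon gamma medians were 3.31 and 4.06. Without any 1 of the 3 anti-IL-1R1 libraries the count was 0, and without combination 1, 2 or 3 it was 388, 658 or 3. None of the named genes above kept its call without any 1 anti-IL-1R1 library. Camera with a preset correlation called 26 lists, 22 higher and 4 lower, led by type I interferon (adjusted p 4.3e-51), with none called when the correlation was estimated (adjusted p 0.0642 for both interferon lists), while fry called 21 lists. Of the lists described here, adjusted over the list alone, 29 type I interferon, 26 interferon gamma, 18 MHC class I, 14 CD40 target, 15 macrophage, 15 mediator, 10 epithelial and 6 hypoxia genes passed.

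Whether anti-IL-1R1 acted differently with and without CD40 agonist was tested as an interaction, the change from CD40 agonist to combination minus the change from untreated to anti-IL-1R1. For interferon and T cell genes, anti-IL-1R1 went on average with lower levels alone and higher levels on top of CD40 agonist. The difference had a median log2 of 2.18 for type I interferon and 2.35 for interferon gamma genes, positive in 29 of 30 and 27 of 27 members. Usp18 had an interaction of 2.97 (SE 0.826), Bst2 of 2.16 (SE 0.613), Ifng of 5.53 (SE 1.45) and Csf1 of 1.67 (SE 0.398). The B and plasma cells list had a median of 2.93 (a call lost without untreated 3, adjusted p 0.0716), T cell genes of 2.48, MHC class I genes of 1.71 and MHC class II genes of 1.41. With anti-IL-1R1 alone the B and plasma cells list was lower with all libraries but called higher without untreated 3. On top of CD40 agonist its levels overlapped, at 0, 1.36 and -0.56 with CD40 agonist and 2.28, 0.16 and 1.26 in the combination. Hypoxia genes were negative in 21 of 21 cases (median -0.58), among them Adm at -1.32 (SE 0.399) and Pdk1 at -0.79 (SE 0.255), and epithelial genes in 17 of 18 (median -0.58), among them Epcam at -6.21 (SE 1.08). The interaction of Diras2 was -1.64 (SE 0.329).

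No single gene passed the interaction test by edgeR, with a lowest adjusted p of 0.905, shared by Epcam, Lrrc26, Gm42502, Diras2 and Egfros, and 849 genes at an unadjusted p under 0.05. DESeq2 called 21 genes, 5 higher and 16 lower, and limma voom 0. Camera with a preset correlation called 22 lists, 18 higher and 4 lower, led by type I interferon (adjusted p 2.92e-40), and none passed with an estimated correlation (adjusted p = 0.128 to 0.252 for the called lists) or by fry. In its mixed form, which asks for change in any direction, fry called epithelial tumour cells (adjusted p 0.0367). Adjusted over the list alone, 24 type I interferon genes and no interferon gamma gene passed, with 1 gene each of the cytotoxic, mediator, epithelial and Schwann cell lists.

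Across the 19436 tested genes, which are not independent replicates, the fold changes that go with anti-IL-1R1 alone and on top of CD40 agonist had a Pearson correlation of 0.00 (exact permutation p 1, adjusted p 1) and a Spearman correlation of 0.08 (exact permutation p 0.82). All 100 relabellings of the libraries within the pairs of groups gave a Pearson correlation at least as large, with a median size of 0.08. The fold changes that go with CD40 agonist, with and without anti-IL-1R1, had a Pearson correlation of 0.40 (exact permutation p 0.04, adjusted p 0.08 over the 2 correlations computed, two-sided) and a Spearman correlation of 0.37 (exact permutation p 0.03, adjusted p 0.06). For the Pearson correlation relabelled libraries gave a median size of 0.13 and a highest of 0.48. Neither passed after adjustment with all libraries. With 1 library left out, the latter correlation ran from 0.25 (adjusted p 0.2, without CD40 agonist 2) to 0.49 (adjusted p 0.02, without CD40 agonist 3).

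**Figure D3:**
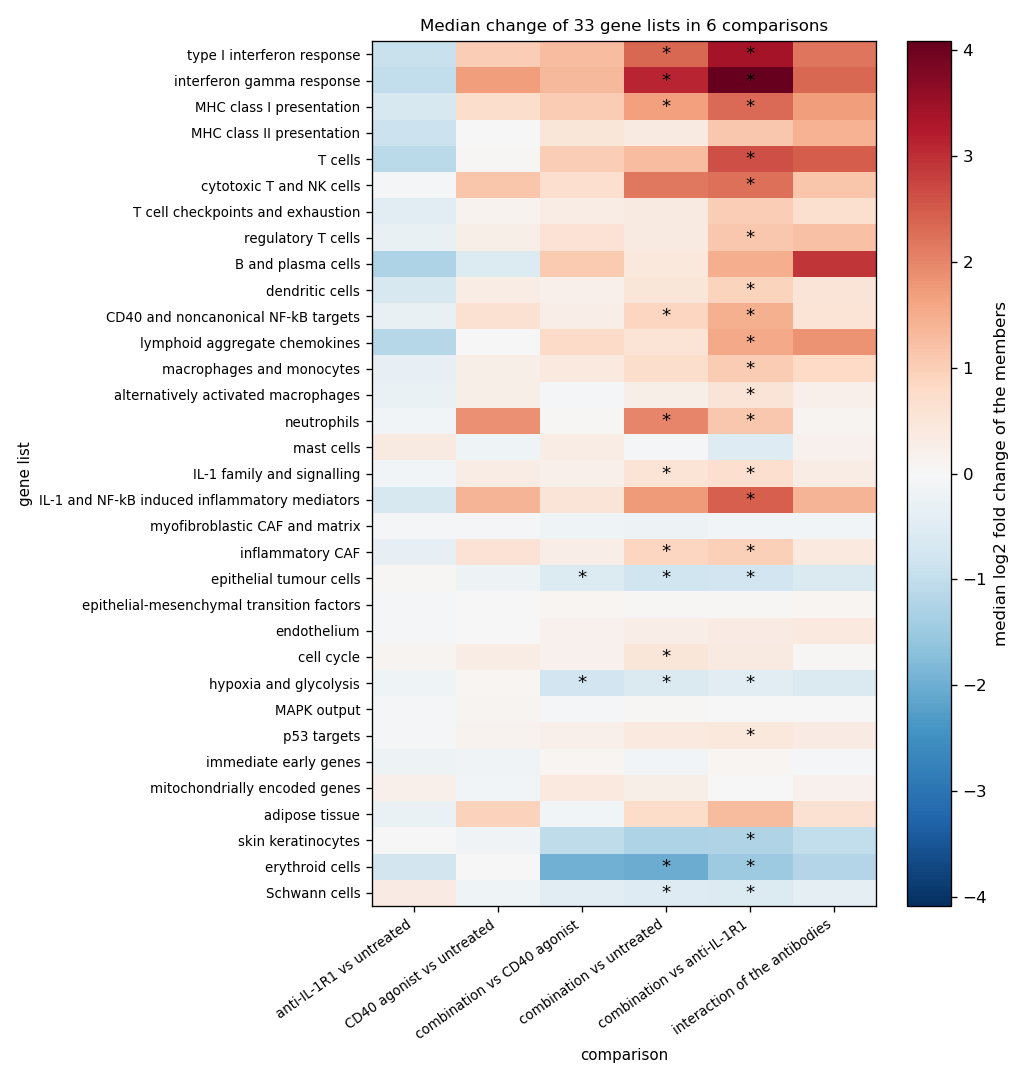
Median log2 fold change of 33 gene lists (vertical axis) in the 5 comparisons and the interaction (horizontal axis), as colour; asterisks mark the 35 medians whose list passed fry at an adjusted p under 0.05, and skeletal muscle genes are left out. The interferon medians run from -1.02 for anti-IL-1R1 against untreated to 4.09 for combination against anti-IL-1R1.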

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

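Of the tests in this part, those of library size and of splits that part the pairs were chosen only after the result was seen. The results below stand out because the change that goes with anti-IL-1R1 differed between tumours with and without CD40 agonist, as tested by the interaction with camera at a preset correlation. Values are medians of the interaction over the members of a list, on the log2 scale.

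The immune lists were positive. They were type I interferon response (2.18), interferon gamma response (2.35), MHC class I presentation (1.71), MHC class II presentation (1.41), T cells (2.48), cytotoxic T and NK cells (1.14), T cell checkpoints and exhaustion (0.66), regulatory T cells (1.2), B and plasma cells (2.93), dendritic cells (0.54), CD40 and noncanonical NF-kB targets (0.56), lymphoid aggregate chemokines (1.84), macrophages and monocytes (0.8), IL-1 family and signalling (0.31), and IL-1 and NF-kB induced inflammatory mediators (1.4). Of stromal and stress lists, inflammatory CAF (0.41), endothelium (0.41) and p53 targets (0.35) were positive. Hypoxia and glycolysis (-0.58), epithelial tumour cells (-0.58), skin keratinocytes (-1.01) and erythroid cells (-1.19) were negative.

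None of these 22 lists passed with an estimated correlation, where their adjusted p ran from 0.128 to 0.252, or by fry, except that fry in its mixed form called epithelial tumour cells (adjusted p 0.0367), and edgeR called no gene. Without CD40 agonist 3 the calls of regulatory T cells (adjusted p 0.0745), IL-1 family and signalling (0.0508) and p53 targets (0.0533) were lost. Medians that moved by more than 1.5 times without it were those of cytotoxic T and NK cells (0.66), checkpoints (0.31), CD40 targets (0.37), IL-1 family (0.17), inflammatory CAF (0.12), p53 targets (0.18) and erythroid cells (-0.56). Without the 2 libraries rich in muscle transcripts they were those of cytotoxic T and NK cells (1.85), CD40 targets (0.88) and p53 targets (0.16). Without combination 1 that of p53 targets was lost (0.106), without combination 2 that of endothelium (0.0615), without combination 3 that of IL-1 family and signalling (0.0697), and without untreated 3 that of B and plasma cells (0.0716). Other assignments of the libraries called as many lists in 6 of 50 splits, the real one included, with 22 lists in the real split and 27 in the highest other, so chance is not excluded. These splits mix same-numbered untreated and anti-IL-1R1 libraries freely, although those deviated together from their group means, which may be chance. Among the 80 splits that part all those pairs, 9 called as many lists, the real one included (a share of 0.112), with 26 in the highest other, so chance is not excluded there either. For genes, all 50 of the 50 splits had at least the real count of 0, and the highest other had 2.

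The type I interferon list, which had the lowest camera p of the interaction though not the largest median, was weighed together with interferon gamma as the pattern of higher interferon lists in combination than in untreated tumours. The tables argue against carried-over skeletal muscle, since the type I interferon median was 2.3 without the 2 libraries rich in muscle transcripts and 2.33 with them. They argue against library size as well, since the lowest total of a combination library, 37.8 M reads, lies within the range of the untreated libraries, 35.4 to 53.3 M. The combination libraries also listed fewer genes with a read, 20410 on average against 23560 in untreated ones, and fewer odd counts, 36.1 to 38.8% against 44.5 to 46.0% among counts of 10 to 100. This difference in the libraries goes with the group, was not tested as a cause and stays open. So do a response to the antibodies and a difference between the tumours that does not come from them, as nothing states how mice were assigned.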

How the results depend on the processing

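The union of genes, voom, the fit without the 2 libraries rich in muscle transcripts and the block with only 2 groups were chosen after the data were seen. In the order anti-IL-1R1 and CD40 agonist against untreated, combination against CD40 agonist, untreated and anti-IL-1R1, and interaction, 1 of 15, 2 of 15, 7 of 15, 12 of 15, 10 of 15 and 1 of 20 alternatives called a gene. For lists these were 9 of 11, 9 of 11, 10 of 11, 10 of 11, 10 of 11 and 15 of 17. With the replicate block edgeR called 0 genes in combination against CD40 agonist, untreated and anti-IL-1R1 (993, 2575 and 2453 at an unadjusted p under 0.05), and Il1a (0.13) and Cd40 (-0.02) in anti-IL-1R1 against untreated and Il1b (-0.04) in combination against CD40 agonist turned sign, none of them called. Without the low-count filter combination against untreated had 71 genes and Il1r1 -0.01. With an estimated correlation camera called 0 lists in anti-IL-1R1 against untreated, 0 in CD40 agonist against untreated, 0, 0 and 0 in combination against CD40 agonist, untreated and anti-IL-1R1, and 0 in the interaction, and fry called 0 lists for each antibody alone, 2 for combination against CD40 agonist and 0 in the interaction. DESeq2 called 8 (CD40 agonist against untreated), 101, 1031 and 1297 (combination against CD40 agonist, untreated and anti-IL-1R1) and 21 genes (interaction). It made 49 false calls in data simulated with the same spread in all groups, unlike the real ones. With only the 2 groups in the fit, edgeR called 0 genes in combination against CD40 agonist and 154 against untreated. With voom these counts were 0 and 50, and 0 against anti-IL-1R1, with Il1a 0.36 and Cd40 -0.02 in anti-IL-1R1 against untreated and Il1r1 0.00 in combination against untreated. Without the muscle-rich libraries the counts were 0 (combination against CD40 agonist) and 153 (against untreated). The block with only untreated and anti-IL-1R1 libraries gave 27 genes and Il1a 0.25. The correlation of the anti-IL-1R1 effects was -0.07 over genes of at least 10 CPM. With 1 library left out, gene counts ran from 0 to 8 (CD40 agonist against untreated), 0 to 5 (combination against CD40 agonist), 0 to 542 (against untreated) and 0 to 658 (against anti-IL-1R1), and list counts from 8 to 25 in combination against CD40 agonist. Then log2 values ran, in anti-IL-1R1 against untreated, from -0.49 to 1.01 (Il1a), -0.14 to 0.13 (Il1b) and -0.08 to 0.09 (Cd40); in CD40 agonist against untreated from -0.07 to 0.12 (Il1r1); in combination against CD40 agonist from -0.12 to 0.07 (Il1r1), -0.38 to 0.29 (Il1b) and -0.15 to 1.06 (Cd40); in combination against untreated from -0.06 to 0.10 (Il1r1); and in the interaction from -0.34 to 0.32 (Il1b) and -0.16 to 1.05 (Cd40). The correlations ran from -0.08 to 0.06 (anti-IL-1R1 effects) and 0.25 to 0.49 (CD40 agonist effects). The cause of these differences was not tested. Of the other values of named genes, 320 of 337, 388 of 396, 339 of 366, 359 of 486, 259 of 445 and 284 of 295 kept direction and side of the threshold, in the order above.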

Other observations

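Of the tests in this part, those on CD40 agonist 3, on splits of pairs, on a lower share of epithelial tumour cells and on a lost subset of tumour cells were chosen only after the results were seen. Several gene lists were not called by camera in any of the 5 comparisons. The factors of epithelial-mesenchymal transition had medians between -0.03 and 0.09 on the log2 scale in the 5 comparisons, MAPK output genes between -0.06 and 0.10, and myofibroblastic CAF and matrix genes between -0.20 and -0.08, and mast cell genes between -0.51 and 0.37. Their members went both ways, so this does not show that they held still. In the combination the myofibroblastic level was 7.77, 8.78 and 7.51, against 8.36 to 8.42 in untreated libraries, and fry in its mixed form, which asks for change in any direction, called mast cells against anti-IL-1R1 (adjusted p 0.0138). Schwann cells were called lower by camera in combination against CD40 agonist (-0.45, adjusted p 0.0351, adjusted p = 0.309 with an estimated correlation, fry 0.0871). Fry called them lower against untreated (-0.54, adjusted p 0.0481) and anti-IL-1R1 (-0.56, adjusted p 0.0166), where camera did not. By camera, alternatively activated macrophages were called higher only in combination against anti-IL-1R1 (0.54, adjusted p 0.0128, 0.0892 with an estimated correlation), and regulatory T cells there (1.11, adjusted p 0.0168, 0.104 with an estimated correlation) and in the interaction.

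Lists of tissues beside the tumour differed as well. Erythroid genes lay at 1.24 ± 0.15 in untreated and -0.02 ± 0.08 in combination libraries as mean log2(CPM + 0.5), a median change of -2.03 (adjusted p 3.54e-05, 0.154 with an estimated correlation, fry 0.0314), which is what less blood in the sample would give, and that was not tested. Genes of the skin keratinocytes list were lower in the combination than in untreated tumours (-1.27, adjusted p 0.0495, 0.304 with an estimated correlation), a call lost without untreated 2 (0.0608), combination 1 (0.115) or combination 3 (0.0916). Adipose tissue genes were called lower with anti-IL-1R1 (-0.27, adjusted p 0.00319, 0.404 with an estimated correlation; 0.225 without anti-IL-1R1 1) and higher with CD40 agonist (0.94, adjusted p 0.00537, 0.503 with an estimated correlation; 0.101 without untreated 1). Immediate early genes were called lower with anti-IL-1R1 (-0.22, adjusted p 0.000227, 0.301 with an estimated correlation), a call lost without anti-IL-1R1 2 (0.12). Mitochondrially encoded genes were called higher in combination than with CD40 agonist (0.41, adjusted p 0.000668, 0.364 with an estimated correlation), a call lost without combination 1 (0.2).

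Combination 1 held immunoglobulin transcripts, with Ighm at 357 CPM and Igkc at 216 CPM, where no other library exceeded 15.2 and 11.6 CPM. Of the genes left out because at least 1 table did not list them, Igkv10-94 had 788 reads in combination 1 and 0 elsewhere, and Ighg3 had 357 there. The muscle myosin gene Myh7 had 413 in combination 1 and 355 in CD40 agonist 2. Krt5 had 133 reads in CD40 agonist 1 and 0 in the other 11 libraries.

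Over all genes CD40 agonist 3 lay near the untreated libraries. Its type I interferon list level was 3.13 beside 4.88 and 5.42 in CD40 agonist 1 and 2, which is below the untreated libraries (3.63 to 4.04) and next to the anti-IL-1R1 ones (2.95 to 3.03), and its Cd40 was 6.51 CPM beside 14.8 and 34.3 CPM. A swap with a library of an untreated or anti-IL-1R1 tumour would leave a CD40 agonist tumour among those 6 libraries, where the highest level was 4.04. That argues against a swapped tumour with a level like CD40 agonist 1 or 2, but cannot test a swapped tumour without a response. The same library under both labels is excluded, since the lowest median chi-square per gene against an untreated library was 12.1. A single wrong label, of an untreated or an anti-IL-1R1 tumour, and a tumour without a response cannot be told apart, as each allows the mean Spearman rho of 0.987 with the untreated libraries that was seen.

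Epcam, Lrrc26, Reg3b and other genes were near 0 reads in all 3 combination libraries. A lower share of epithelial tumour cells is argued against as the whole cause for Epcam, since the other epithelial genes had a median log2 change 5.52 above that of Epcam. Because Epcam was picked for its near loss, part of this gap follows from the choice. The value does not cover Lrrc26 or Reg3b. Random loss in libraries of few distinct molecules stays open. Of 14226 genes, 4 (Lrrc26, Ear2, Cyp2j5 and Ttr; Ear2 has close paralogs) were at or below 0.1 CPM in all 3 libraries against 0.106 expected from independent loss, a ratio of 37.7. That is above the bound of 5 set before. The expected number was summed within bins of genes of like mean CPM in untreated and anti-IL-1R1 libraries. It took no account of genes within a bin differing in how readily they are lost in every such library. Putting CD40 agonist 1 in place of a combination library gave ratios of 53.2 to 105, and Epcam and Reg3b are not among the 4. A lost subset of tumour cells, which the choice of these 4 genes cannot test, cannot be told apart from it.

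The combination libraries and CD40 agonist 1 listed fewer genes with a read, 19578 to 20857 and 20364, than the other 8 libraries, 21731 to 24497. The numbers of genes with at least 10 reads overlapped, at 17282 to 18265 and 18262 against 17297 to 18873. Among counts from 10 to 100, odd counts made up 36.1 to 38.8% in the combination libraries and 36.4% in CD40 agonist 1, against 42.0 to 47.4% elsewhere, where 50% would hold if reads were counted independently. The cause was not tested.

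Splits of 3 against 3 libraries number 10, too few for a share under 0.05. For genes, the real count and the highest of the other splits were 0 and 0 (anti-IL-1R1 against untreated, 10 of the 10 splits as large), 0 and 0 (CD40 agonist against untreated, 10 of the 10), 1 and 4 (combination against CD40 agonist, 3 of the 10), 12 and 0 (combination against untreated, 1 of the 10) and 474 and 445 (combination against anti-IL-1R1, 1 of the 10). The split with 445 genes set anti-IL-1R1 1 and 3 with combination 2 against the rest, which points to a structure of the samples. For lists, they were 18 and 18 (2 of the 10), 14 and 23 (6 of the 10), 21 and 26 (2 of the 10), 18 and 21 (3 of the 10) and 26 and 24 (1 of the 10), in the same order. These counts use the fit without a block and take no account of same-numbered untreated and anti-IL-1R1 libraries deviating together. That pairing was found in these data and may be chance. Over all groups 5 of 18 same-numbered pairs were best with their own number, where each had 3 libraries to choose from. Of the 10 splits of untreated and anti-IL-1R1 libraries, 4 part all same-numbered pairs, again too few for a share under 0.05. The other 6 keep a pair within a group. In a comparison chosen after the results were seen, the block with only these 2 groups called 27 genes and 20 lists in the real split and 0 genes in each of the other 3, which had 671, 396 and 541 genes at an unadjusted p under 0.05 and 5, 15 and 9 lists. Without the block these 3 splits called 3, 13 and 8 lists, and the split that equalled the real 18 kept the pair numbered 1 together.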
